A study of Arabidopsis thaliana with 6 samples.

How the data were processed

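RNA was sequenced from whole Arabidopsis thaliana seedlings that were 4 days old and had grown at 22 °C in continuous darkness after a cold, dark period. Of the 6 libraries, 3 were labelled wild type and 3 were labelled atino80-6, a line named after INO80 (AT3G57300), the ATPase of the INO80 chromatin remodelling complex. Total RNA was extracted with TRIzol, treated with DNase and made into libraries with a TruSeq RNA kit. The labels state neither whether the kit kept the strand of the transcripts nor whether the replicates were separate cultures, so the p-values measure only the spread between samples.

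The authors' notes list FastQC, cutadapt, HISAT2, SAMtools, featureCounts, DESeq2 and deepTools and the TAIR10 genome build, without versions and without naming the annotation. The authors deposited an expression table with FPKM values, scaled between libraries with DESeq2 size factors. The authors also deposited a DESeq2 comparison of atino80-6 with wild type. Per the file headers this table holds a mean signal over the libraries, the log2 fold change and its error on the log2 scale, a score (the change divided by its error), the p-value and the adjusted p-value. The design assumed normalized values, whereas the deposited file held FPKM, so the authors' normalized counts were recovered by multiplying each FPKM value by the gene's mean signal over its mean FPKM. Undoing the size factors then gave whole reads for 146922 of 146922 values, within 0.01 reads. Size factors of the recovered reads were the median-of-ratios factors to within a relative difference of 2.3e-12. The files held 24487 genes, of which 24255 (99.1%) were matched by identifier to the reference annotation for names, products, strand and order. Because that annotation is of the build TAIR10.1 and the authors' build is TAIR10, no coordinates are printed.

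The recovered reads per library ranged from 18446028 to 24156610. A gene with 0 reads in a group was given a floor of 3 reads over the group, and its fold is a lower bound. A gene with 1 to 3 reads in a group is given as a ratio with an exact 95% interval. A count of 3 reads in a single library corresponded to between 2.62 and 3.5 normalized counts. Intervals and floors cover counting error only.

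Genes with a mean of at least 10 normalized counts over the 6 libraries were tested (20222 genes). Normalized counts plus a pseudocount of 1 were put on the log2 scale and fitted with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with a trend on abundance), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A gene is said to have risen or fallen when it passed this threshold and was higher or lower in the libraries labelled atino80-6 than in those labelled wild type, and errors of log2 changes are standard errors of the fit with 3 libraries per group. Folds are ratios of the group means of normalized counts, and log2 changes are differences of mean log2 values with the pseudocount. The gene lists numbered 31, of which 29 were written by hand and the other 2 held the chloroplast and the mitochondrial identifiers. Each list with at least 3 tested members was compared with all other genes by limma's camera test with a preset correlation between genes of 0.01, adjusted over the 31 lists, and again with an estimated correlation. For each list the number of members past the threshold is also given adjusted over the list alone. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

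The groups, the test, the threshold, the gene lists, the rule for naming genes and all alternatives except 2 were chosen before the data were examined. The rule named INO80, HY5, COP1, DET1 and PHYA whatever their result. It added the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold with a mean of at least 50 and no overlap between the genotypes. From each list it took the members past the threshold with the largest change, up to 4 from a list with at least 3 such members or past the list test and up to 2 from any other. Further genes named in parentheses as members of a list, and AT3G57310, EIF3E, ELIP1, ELIP2, PORA and PORB, were chosen after their values were seen.

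The alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, equal library totals, quantile normalization, TMM factors computed on the recovered reads, limma voom on these reads, robust empirical Bayes, the repeat number as a block, each of the 6 libraries left out, an estimated correlation and the fry test for the lists, and a 2-fold limit for the overlap with the authors' table. The 2 added after seeing the data were the FPKM values as deposited and the fit without wild type 1 and atino80-6 3, which stood apart from the other libraries of their groups. The planned fits with 2 count models were not run, although whole reads were recovered, because count models were reserved for deposited counts. The procedure was tested on simulated data with 200 changed genes among 20222. It recovered 70% of 60 genes changed 1.5-fold, 90% of 70 genes changed 2-fold and 100% of 70 genes changed 4-fold. It called 3 of 20022 unchanged genes, which was 1.7% of its calls, and 0 of 100 unshifted lists. The simulated genes varied independently of each other, whereas the estimated correlation was 0.65 in the photosynthesis list and 0.78 in the seed storage list. The simulated lists therefore do not show how often camera calls lists whose members vary together. The simulation also held no library that stood apart and gave genes of like abundance the same spread. It changed 200 genes, whereas 34.2% of the tested genes were called in the data. Its shares of recovered genes and false calls need not hold for these data.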

Results

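Transcript levels were measured in 4-day-old dark-grown seedlings, in 3 libraries labelled wild type and 3 labelled atino80-6. The wild type libraries held 23057681, 21804473 and 24156610 reads and the libraries labelled atino80-6 held 18446028, 21569743 and 18860855. The first principal component of the 20222 tested genes separated the groups and carried 74.9% of the variance. Within the groups, wild type 1 and atino80-6 3 stood apart. A chi-square per degree of freedom between replicates was 21.6 and 21.3 for wild type 1 against the others but 6.01 between wild type 2 and 3. It was 24.2 and 22.1 for atino80-6 3 against the others but 8.40 between atino80-6 1 and 2. Reads from organelle genes made up 0.192% of atino80-6 3 (95% Wilson interval 0.190 to 0.194) and between 0.0627% and 0.0967% of the other libraries.

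The comparison of the genotypes asks which transcripts of dark-grown seedlings differ between wild type and the atino80-6 line, which is named after INO80. INO80 itself was higher, not lower, in the libraries labelled atino80-6, with 31503 ± 2887 normalized counts (SD, n = 3) against 5839 ± 302 in wild type (SD, n = 3). The ratio of the means was 5.40 and the log2 change 2.43 ± 0.10 (limma adjusted p = 2.8e-06). The 3 wild type libraries held 5586, 6173 and 5758 normalized counts, and the libraries labelled atino80-6 held 28174, 33013 and 33322. A higher transcript goes against what a loss of the gene's transcript would give, and the labels do not state what kind of allele atino80-6 is, so each direction rests on the labels as deposited. AT3G57310, the next gene downstream of INO80 and on the opposite strand, chosen after its values were seen, had 0 reads in wild type and 45.6, 70.7 and 75.1 normalized counts in the libraries labelled atino80-6, at least 70.9-fold higher; whether the reads kept their strand is not stated. DET1, a repressor of light responses in the dark, rose 1.84-fold from 553 ± 1.52 to 1019 ± 67.8 normalized counts (SD, n = 3 each; adjusted p = 8.4e-05). HY5, a transcription factor that promotes light-type development, had 757 normalized counts in wild type and 615 in the libraries labelled atino80-6, a log2 change of -0.29 that did not pass the test (adjusted p = 0.089). COP1, the ubiquitin ligase that removes HY5 in the dark, stood at 0.12 (adjusted p = 0.25) and the light receptor PHYA at 0.21 (adjusted p = 0.15). PHYA passed in the authors' deposited table (0.21, adjusted p = 0.032) and in limma without wild type 1 and atino80-6 3 (0.26, adjusted p = 0.021).

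**Figure D1:**
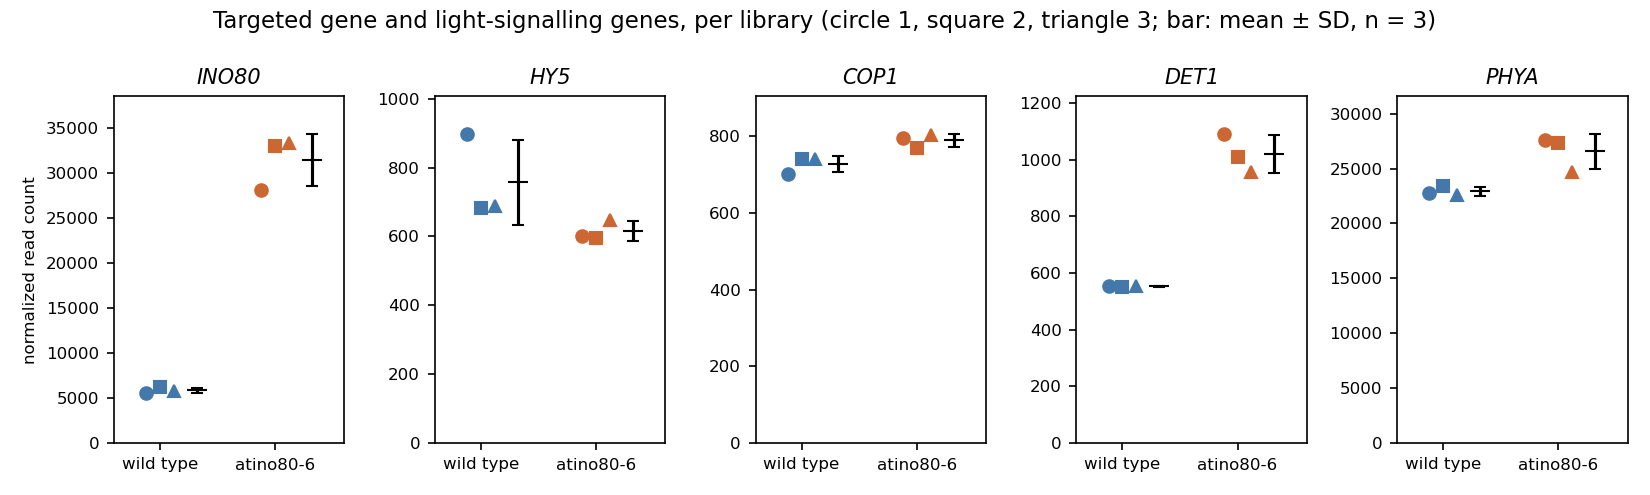
Normalized counts of INO80, HY5, COP1, DET1 and PHYA in each library, by genotype label, with group means and bars of 1 SD (n = 3). The libraries labelled atino80-6 lie between 28174 and 33322 for INO80, all above the highest wild type library at 6173.

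Across the transcriptome 3572 genes rose and 3351 fell in the libraries labelled atino80-6, together 34.2% of the 20222 tested. A change of at least 2-fold was reached by 1351 of the genes that rose and 1073 of those that fell, and the median size of a called change was 0.73 on the log2 scale. The genotypes did not overlap for 9767 genes (48.3%), where chance gives 10%. Without wild type 1 and atino80-6 3, limma called 4435 genes higher and 4384 lower. The authors' deposited table had 3628 genes higher and 3416 lower, and 3369 were higher and 3168 lower there and in limma. The remaining 386 genes passed in limma alone, and 0 genes passed in opposite directions.

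**Figure D2:**
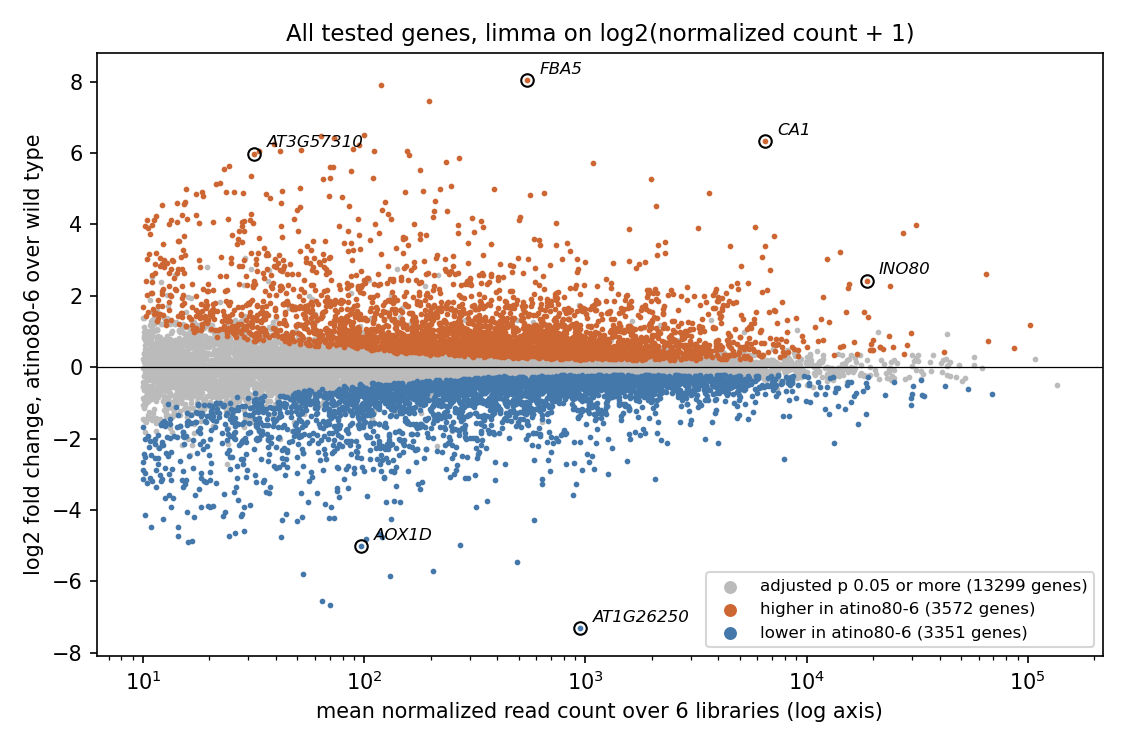
Log2 fold change (atino80-6 over wild type) of each of the 20222 tested genes against its mean normalized count on a log axis, with genes past the threshold coloured by direction. The 3572 higher and 3351 lower genes lie on either side of a median change of 0, and INO80 sits at 2.43.

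The genes with the largest rises included FBA5, a fructose-bisphosphate aldolase, which went from 3.77 to 1083 normalized counts (287-fold, log2 change 8.04 ± 0.44). The carbonic anhydrase gene CA1 rose 79.9-fold from 161 ± 45.9 to 12823 ± 1604 normalized counts (SD, n = 3 each). The protein kinase gene CIPK20 rose 161-fold, the transporter gene UMAMIT14 123-fold, the defence peptide gene THI2.2 120-fold and the resistance-type gene AT5G46490 99.5-fold. Their wild type means were 1.23, 1.53, 3.25 and 1.78 normalized counts, so these folds rest on few wild type reads. AT2G15020, of unknown function, had 0 reads in the 3 wild type libraries and 239 ± 13.5 normalized counts in those labelled atino80-6 (SD, n = 3), at least 264-fold higher. With 1 to 3 wild type reads, AT1G70820 was 210-fold higher (95% interval 57.6 to 1739), AT4G06566 468-fold (83.5 to 18525) and AT4G16870 171-fold (46.9 to 1419). Adjusted p in limma was at most 0.00023 for these 10 genes. Among them, single libraries moved the log2 change most for THI2.2 and AT4G06566. THI2.2 stood at 8.60 without wild type 2 (7.46 with it), and AT4G06566 at 5.66 without atino80-6 1 and 7.03 without atino80-6 3 (6.43 with them).

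Among the largest falls were a pair of neighbouring extensin genes, whose products are structural cell wall proteins. AT1G26250 went from 1884 ± 826 to 11.9 ± 9.46 normalized counts (SD, n = 3 each), 159-fold lower, with a log2 change of -7.32 ± 0.50. AT1G26240, with 1 read in the libraries labelled atino80-6, was 347-fold lower (95% interval 61.9 to 13723), and reads of these related genes are not told apart with certainty. The peroxidase gene AT3G03670, also with 1 read, was 383-fold lower (68.4 to 15161). The receptor kinase gene AT1G05700 fell 62.4-fold, the subtilase gene AT4G10510 54.9-fold, the berberine-bridge-type oxidase gene AT1G26410 53.8-fold and the germin-like gene GLP9 26.7-fold. AT1G05700 and AT4G10510 had means of 4.15 and 1.9 normalized counts in the libraries labelled atino80-6, so their folds rest on few reads. AOX1D, a mitochondrial alternative oxidase, AT4G12735, of unknown function, and the cytochrome P450 gene CYP82C2 had log2 changes of -5.02, -5.0 and -4.81. Adjusted p in limma was at most 0.004 for these 10 genes. AOX1D and AT4G12735 were high in wild type 1 (438 and 1254 normalized counts, against at most 105 and 231 in wild type 2 and 3), and without it their changes were -4.05 and -4.03; without wild type 2 they were -5.94 and -5.70, and limma voom on the reads did not call them (adjusted p = 0.11 and 0.10). Without atino80-6 3 the changes of AT4G10510, AT1G26410, GLP9 and CYP82C2 were -6.71, -6.37, -6.56 and -5.86; GLP9 stood at -4.58 without atino80-6 1, and CYP82C2 at -4.09 without wild type 3 and -4.10 without atino80-6 2.

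Nuclear genes of the photosynthetic apparatus were the list that stood farthest from other genes, with 42 of 43 tested members higher in the libraries labelled atino80-6, 0 lower and a median log2 change of 2.00. LHCB1.4, a light-harvesting protein of photosystem II, rose 52.9-fold from 40.4 ± 11.8 to 2135 ± 341 normalized counts (SD, n = 3 each), and RBCS1B, a small subunit of Rubisco, rose 39.2-fold. LHCB2.1 and LHCB1.1 rose 23.4-fold and 20.2-fold. These 4 genes have near-identical copies, so the share of each copy is uncertain. The list passed limma's camera test with the preset correlation (adjusted p = 1.8e-26), and adjusted p = 0.48 with an estimated correlation. Adjusted over the list alone, 43 members were higher.

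**Figure D3:**
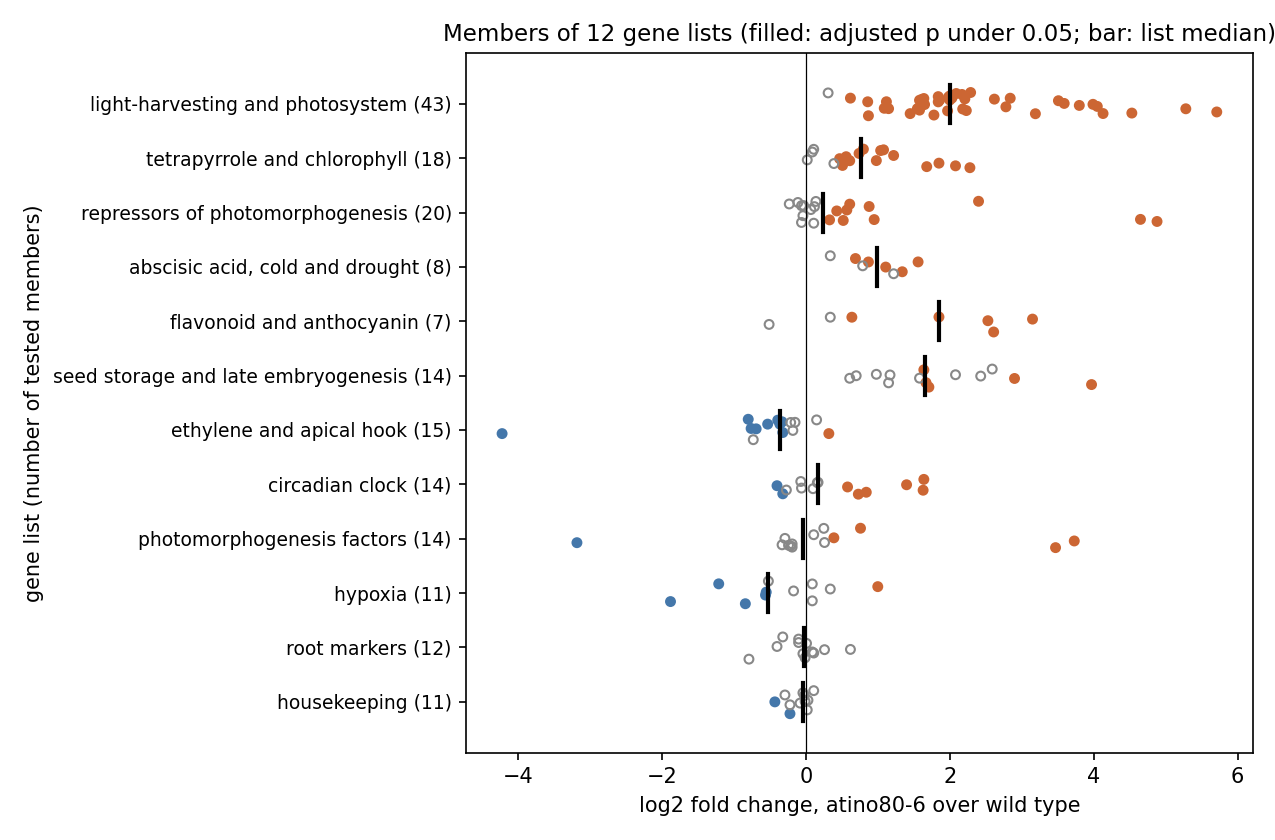
Log2 fold changes (atino80-6 over wild type) of the tested members of 12 of the gene lists, 1 circle per gene, filled where the gene passed the limma threshold and open where it did not, with a bar at each list's median. The photosynthesis list has a median of 2.00 and the ethylene list a median of -0.36, and root markers sit around -0.02.

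Genes of tetrapyrrole and chlorophyll synthesis rose in 14 of 18 tested members and fell in 0, with a median log2 change of 0.77. GUN5, the large subunit of magnesium chelatase, rose 4.82-fold from 1561 ± 214 to 7520 ± 251 normalized counts (SD, n = 3 each). The divinyl reductase gene DVR rose 4.2-fold, the cyclase gene CRD1 3.57-fold and GUN4, a chelatase cofactor, 3.20-fold. PORA and PORB, which encode the light-dependent protochlorophyllide reductases, stood at 0.11 (adjusted p = 0.71) and 0.39 (adjusted p = 0.11). PORA was at -0.05 without atino80-6 2, and PORB passed without wild type 1 (0.54, adjusted p = 0.034) or without atino80-6 1 (0.56, adjusted p = 0.032). The list passed camera (adjusted p = 1.1e-06; adjusted p = 0.63 with an estimated correlation), and adjusted over the list alone 14 members were higher.

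Flavonoid and anthocyanin genes rose in 5 of 7 tested members and fell in 0, with a median log2 change of 1.85. FLS1, flavonol synthase, rose 9.84-fold from 7.63 ± 1.90 to 75.1 ± 13.8 normalized counts (SD, n = 3 each). CHS, the entry enzyme of the pathway, rose 6.38-fold, the glucosyltransferase gene UGT78D2 5.95-fold and CHI 3.5-fold. Camera gave adjusted p = 0.015 (adjusted p = 0.48 with an estimated correlation), and 5 members were higher adjusted over the list alone. The call ended among genes with a mean of at least 50, where 4 members remained tested (adjusted p = 0.14).

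Known repressors of light-type development rose in 10 of 20 tested members in the libraries labelled atino80-6 and fell in 0, with a median log2 change of 0.24. BBX32 was 62.1-fold higher (95% interval 20.8 to 304, with 3 wild type reads), and the related B-box gene BBX25 rose 25.6-fold from 15.8 ± 6.58 to 404 ± 98.2 normalized counts (SD, n = 3 each). PIF7, a phytochrome-interacting factor, rose 5.84-fold and SPA3, a partner of COP1, 1.93-fold. Camera gave adjusted p = 0.007 (adjusted p = 0.48 with an estimated correlation), and 10 members were higher adjusted over the list alone. The call ended among genes with a mean of at least 50 (18 members, adjusted p = 0.059).

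Transcription factors that promote light-type development moved both ways, 4 of 14 tested members up and 1 down. HYH, the close relative of HY5, rose 13.7-fold from 24.3 ± 4.62 to 333 ± 30.9 normalized counts (SD, n = 3 each), the GATA factors CGA1 and GNC rose 12.3-fold and 1.69-fold, and the MYB gene LAF1 fell 9.88-fold. The list's median was -0.04 and its mean 0.31, and camera, which pointed up, did not pass (adjusted p = 0.66). Of 13 photoreceptor genes 4 rose and 1 fell (median 0.07, adjusted p = 0.31): PHOT2 rose 2.13-fold, PHYB 1.35-fold and ZTL 1.25-fold, and FKF1 fell 1.49-fold. The calls of FKF1 and ZTL were lost without single libraries, at most at adjusted p = 0.10 for FKF1 without wild type 2 (also without wild type 3, atino80-6 2 or atino80-6 3) and at 0.059 for ZTL without atino80-6 2. Counts adjusted over the list alone were 4 up and 1 down for each of these lists. Limma called 4 transcription factors up and 2 down without atino80-6 3, and of the photoreceptors 3 up and 0 down without wild type 2 or 3, 2 up and 0 down without atino80-6 2, and 5 up and 0 down without atino80-6 3.

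Clock genes changed in 8 of 14 tested members, 6 up and 2 down. RVE1, CCA1 and LHY, which encode related morning-phased MYB factors, rose 3.16-fold, 3.1-fold and 2.64-fold, and LNK2 rose 1.77-fold. CCA1 went from 727 to 2250 normalized counts. The list had a median of 0.16 and did not pass camera (adjusted p = 0.11), and the counts were 6 and 2 adjusted over the list alone. The clock genes that fell numbered 0 without wild type 3 and 1 without any other single library except wild type 1. Floral repressors and integrators rose in 4 of 9 tested members and fell in 0 (median 0.31, adjusted p = 0.23; 4 and 0 adjusted over the list alone). SOC1 rose 4.35-fold, SVP 3.19-fold, MAF5 1.48-fold and FLC 1.24-fold, and MAF5 has near-identical neighbours. FLC lost its call without any of 5 libraries, that is each except atino80-6 3 (adjusted p at most 0.11, without atino80-6 1), and with equal library totals (adjusted p = 0.053).

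Subunits of the INO80 complex and of the related SWR1 complex passed the test in 2 of 15 tested members, both higher. Beside INO80, ARP5, an actin-related subunit of the INO80 complex, rose 1.46-fold from 318 ± 14.6 to 464 ± 17.9 normalized counts (SD, n = 3 each). The list's median was 0.02 (-0.03 with equal library totals and -0.01 after quantile normalization) and camera gave adjusted p = 0.53. Among 12 other SNF2-family remodellers 1 rose and 2 fell (median -0.08, adjusted p = 0.40). CHR17 fell 1.53-fold, CHR12 fell 1.24-fold and CHR23 rose 1.34-fold. Adjusted over the list alone the counts were 2 and 0 for the first list and 1 and 2 for the second. Without atino80-6 1 limma also called 1 member of the first list lower; the second list had 0 up and 1 down without wild type 2, and 1 and 1 without wild type 3 or atino80-6 2. CHR23 lost its call without wild type 2 (adjusted p = 0.056), and CHR12 without wild type 2, wild type 3 or atino80-6 2 (at most 0.092).

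Genes of ethylene signalling and the apical hook fell in 9 of 15 tested members and rose in 1, with a median log2 change of -0.36. ERF1, an ethylene response factor, fell 30.4-fold, from 299, 36.1 and 68.2 normalized counts in wild type to 2.34, 2.99 and 7.97 in the libraries labelled atino80-6. The receptor gene ETR2 fell 1.75-fold, EBF1, an F-box gene that limits ethylene responses, 1.69-fold and the ACC oxidase gene ACO1 1.6-fold; EIL1 was the member that rose (0.32). Camera gave adjusted p = 0.0093 (adjusted p = 0.48 with an estimated correlation), and adjusted over the list alone 1 member was higher and 10 lower. Without wild type 1 the change of ERF1 was -3.36 and without wild type 2 -4.87 (-4.22 with them), and limma voom did not call it (adjusted p = 0.063). The members that fell numbered 5 without wild type 3 or without atino80-6 1, and 6 without atino80-6 3, while the list still passed camera with the preset correlation (adjusted p at most 0.027 over the 18 alternative fits). ACO1 lost its call without wild type 1, wild type 3, atino80-6 1 or atino80-6 3 (adjusted p at most 0.11).

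Auxin-responsive genes fell in 5 of 19 tested members and rose in 1. IAA5 fell 1.75-fold, IAA1 1.53-fold and GH3.5 1.48-fold, while IAA29 rose 1.52-fold. In the list of auxin synthesis and transport, the influx carrier gene AUX1 fell 1.51-fold from 4265 ± 333 to 2832 ± 326 normalized counts (SD, n = 3 each) and was the single call among 12 tested members; without wild type 1 and atino80-6 3 there were 6, all lower, and with equal library totals 3. The medians were -0.11 and -0.17, camera gave adjusted p = 0.42 and 0.29, and the counts adjusted over the list alone were 1 up and 5 down and 0 up and 1 down. The auxin-responsive counts were 2 up and 4 down without wild type 1, 0 and 3 without wild type 2, 0 and 4 without wild type 3, 2 and 3 without atino80-6 1, and 0 and 3 without atino80-6 2. In the transport list 3 members fell without wild type 1 and 4 without atino80-6 3. Leaving out single libraries ended the calls of GH3.5 (highest adjusted p = 0.15, without wild type 3; also without wild type 2, atino80-6 1 or 2), IAA5 (0.13, without atino80-6 2; also without wild type 1, wild type 2 or atino80-6 1) and IAA29 (0.069, without atino80-6 2; also without wild type 2 or 3).

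Cell wall genes of elongating tissue (expansins, xyloglucan endotransglucosylases and primary-wall cellulose synthases) rose in 9 of 21 tested members and fell in 2, with a median of 0.24. EXPA2 rose 7.79-fold, EXPA5 2.77-fold, XTH22 2.45-fold and XTH17 2.03-fold. EXPA2 held 483, 333 and 83.1 normalized counts in the libraries labelled atino80-6, and its log2 change was 3.55 without atino80-6 3 and 2.80 with it. Camera gave adjusted p = 0.16, and 0.043 without atino80-6 1; adjusted over the list alone 10 were higher and 2 lower. Gibberellin genes rose in 4 of 13 tested members and fell in 2 (median 0.23, adjusted p = 0.42; 6 and 2 adjusted over the list alone). The biosynthesis genes GA3OX1 and GA20OX1 rose 3.13-fold and 1.64-fold, the gibberellin-responsive GASA1 rose 1.5-fold and GA2OX6, which encodes an inactivating enzyme, fell 1.62-fold. Brassinosteroid genes passed in 3 of 12 tested members, CPD (1.61-fold) and BR6OX2 (1.6-fold) up and BZR1 (1.34-fold) down (median 0.05, adjusted p = 0.61; 2 and 1 adjusted over the list alone). With equal library totals or quantile normalization 2 brassinosteroid genes rose and 3 fell, and without wild type 1 and atino80-6 3 they were 4 and 3. Single libraries moved the brassinosteroid counts to 3 up and 2 down (without wild type 1), 3 and 3 (without atino80-6 3) or 2 and 0 (without any of the others). GASA1 lost its call without wild type 3 or atino80-6 2 (adjusted p at most 0.080), and BZR1 without wild type 2, wild type 3, atino80-6 1 or atino80-6 2 (at most 0.071).

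Genes of the abscisic acid, cold and drought response rose in 5 of 8 tested members and fell in 0, with a median log2 change of 0.99. The dehydrin gene RAB18 rose 3.25-fold, from 8244, 5551 and 7494 normalized counts to 28473, 30715 and 9971. RD29A rose 2.55-fold, RD29B 2.21-fold and the dehydrin gene ERD10 1.83-fold. Camera gave adjusted p = 0.007 (adjusted p = 0.48 with an estimated correlation), and 6 members were higher adjusted over the list alone. The members that rose numbered 3 without wild type 2 or without atino80-6 2 and 7 without atino80-6 1, and the list passed camera with the preset correlation each time (adjusted p at most 0.02 over the 18 alternative fits). RAB18 lost its call without wild type 2 (adjusted p = 0.054), without atino80-6 2 (0.055) and with robust empirical Bayes (0.066).

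Seed storage, oil body and late embryogenesis genes rose in 5 of 14 tested members and fell in 0, with a median log2 change of 1.65. SESA1, a seed storage albumin, rose 20.2-fold, the seed maturation factor FUS3 11.8-fold, the late embryogenesis gene EM6 3.75-fold and the oleosin gene OLEO2 3.67-fold. Atino80-6 3 held less of these than the other libraries of its label: OLEO2 stood at 2049, 2411 and 571 normalized counts and EM6 at 8452, 9187 and 1960. Camera gave adjusted p = 0.015 (adjusted p = 0.79 with an estimated correlation), and 5 members were higher adjusted over the list alone. Without wild type 1 and atino80-6 3, 13 of 14 members rose (median 2.55, adjusted p = 0.00024). Leaving out atino80-6 3 alone gave 11 members higher, and leaving out wild type 2, wild type 3, atino80-6 1 or atino80-6 2 gave 3. The list did not pass camera without wild type 2 (0.088), without atino80-6 2 (0.051) or among genes with a mean of at least 50 (0.13). With all libraries it did not pass the fry test (adjusted p = 0.17). OLEO2 and EM6 lost their calls without wild type 2 or 3 or atino80-6 1 or 2, EM6 also without wild type 1 (adjusted p at most 0.12 and 0.14, both without atino80-6 2), and stood at 2.36 and 2.39 on the log2 scale without atino80-6 3 against 1.71 and 1.67 with it. SESA1, which has near-identical neighbours, was at 3.37 without wild type 3 and 4.62 without atino80-6 3 (3.97 with them). Its wild type mean was 3.96 normalized counts, so its fold rests on few wild type reads.

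Genes that mobilise seed reserves passed in 6 of 11 tested members, 4 up and 2 down. The glyoxylate cycle genes MLS and ICL rose 2.67-fold and 2.26-fold, ICL from 62715 to 141577 normalized counts, and the beta-oxidation gene MFP2 rose 1.38-fold. The lipase gene SDP1 fell 1.27-fold. The list's median was 0.03 (-0.01 with equal library totals or quantile normalization), camera gave adjusted p = 0.58, and 5 were higher and 2 lower adjusted over the list alone. The counts were 2 up and 1 down without wild type 2, atino80-6 1 or atino80-6 2, and 4 and 1 without wild type 3. MFP2 lost its call without wild type 1, wild type 2, atino80-6 1 or atino80-6 2 (adjusted p at most 0.078).

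**Figure D4:**
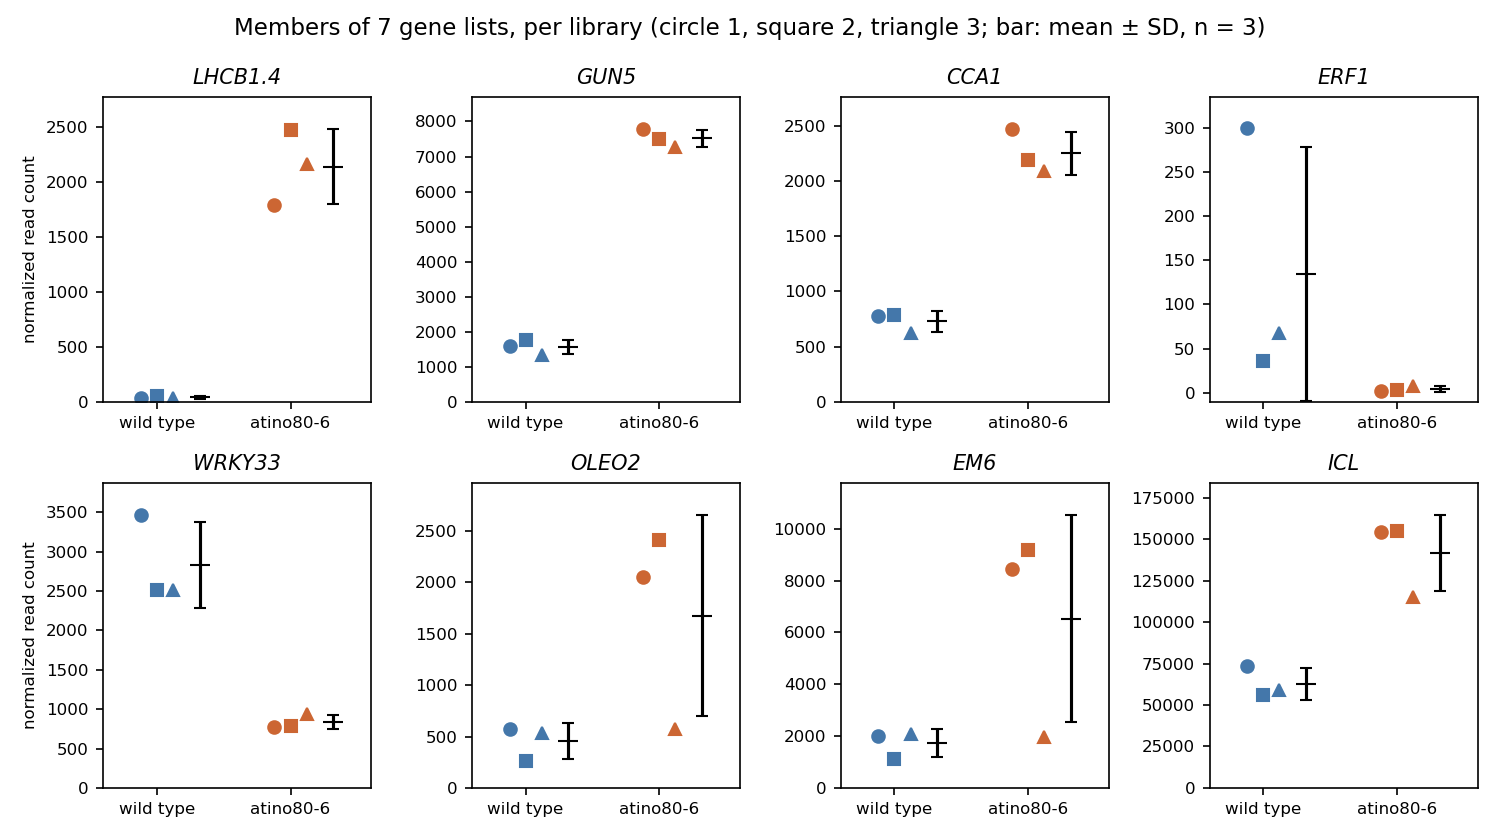
Normalized counts of LHCB1.4, GUN5, CCA1, ERF1, WRKY33, OLEO2, EM6 and ICL in each library (circle, square and triangle for replicates 1, 2 and 3), by genotype label, with the group mean and a bar of 1 SD (n = 3). LHCB1.4 lies between 1784 and 2465 in the libraries labelled atino80-6 against at most 53.7 in wild type, while OLEO2 and EM6 are low in atino80-6 3 (571 and 1960).

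Hypoxia genes fell in 5 of 11 tested members and rose in 1. Sucrose synthase SUS4 fell 3.97-fold, the haemoglobin gene HB1 2.34-fold and the oxygen-sensing oxidase gene PCO1 1.82-fold, and SRO5 rose 2.02-fold. The list had a median of -0.52 and camera gave adjusted p = 0.23, with 1 and 5 adjusted over the list alone. SRO5 lost its call without atino80-6 2 (adjusted p = 0.058), leaving 0 up and 5 down. Wounding, touch and defence genes split into 3 up and 3 down of 9 tested. PR1, a marker of salicylic acid responses, rose 14.0-fold, the vegetative storage protein genes VSP2 and VSP1 6.42-fold and 2.36-fold, and WRKY33, a defence regulator, fell 3.39-fold; reads of VSP1 and VSP2 are not told apart with certainty. The median was -0.60 and the mean 0.15, camera pointed down without passing (adjusted p = 0.59), and 3 were higher and 5 lower adjusted over the list alone. VSP1 did not pass without wild type 1 and atino80-6 3 (adjusted p = 0.060), and the defence counts were then 2 up and 4 down. Of 10 heat shock genes HSP22 fell 2.57-fold and the others did not pass (median -0.18, adjusted p = 0.59; 0 and 0 adjusted over the list alone). HSP22 lost its call without wild type 2, atino80-6 1 or atino80-6 3 (adjusted p at most 0.080). Without atino80-6 2 the heat shock list passed camera with the preset correlation, with 4 members lower (median -0.50, adjusted p = 0.028). With an estimated correlation and all libraries, camera gave this list adjusted p = 0.87. Without atino80-6 3 limma called 3 heat shock genes higher and 0 lower, and without wild type 1 and atino80-6 3 it called 1 higher and 0 lower (median -0.05, camera up, adjusted p = 0.91).

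DNA damage response genes rose in 5 of 19 tested members and fell in 1. GMI1, a repair gene induced by irradiation, rose 5.43-fold from 92.7 to 504 normalized counts, the cell cycle inhibitor gene SMR5 rose 3.42-fold and XRI1 1.51-fold, and KU70 fell 1.5-fold. The list's median was 0.21 and camera gave adjusted p = 0.27 (5 and 1 adjusted over the list alone). Cell cycle and replication genes passed in 4 of 12 tested members: CYCD3-1 rose 1.54-fold and CDKB2-1, MCM2 and MCM7 fell 1.63-fold, 1.38-fold and 1.36-fold (median -0.03, adjusted p = 0.59; 1 and 4 adjusted over the list alone). The cell cycle counts were 1 up and 1 down without wild type 1, 0 and 1 without wild type 2 or atino80-6 2, and 0 and 0 without wild type 3 or atino80-6 1. With equal library totals they were 0 up and 4 down and after quantile normalization 1 and 4, and those of the DNA damage list 4 and 1 and 4 and 2. CYCD3-1 lost its call with equal library totals (adjusted p = 0.056), as did XRI1 (0.05), which also lost it after quantile normalization (0.051). These 4 and XRI1 lost their calls without single libraries, the highest adjusted p being 0.12 for CYCD3-1 without wild type 2, 0.12 for MCM2 and MCM7 without wild type 3, 0.11 for CDKB2-1 without wild type 2 and 0.11 for XRI1 without atino80-6 1. Of the 6 libraries, those that could be left out without ending the call were wild type 1 and atino80-6 3 for CYCD3-1 and CDKB2-1, wild type 2 and atino80-6 3 for MCM7, atino80-6 2 for MCM2 and atino80-6 3 for XRI1.

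Root hair and endodermis markers passed in 0 of 12 tested members with limma (median -0.02, mean -0.06, camera up, adjusted p = 0.99; 0 and 0 adjusted over the list alone), and without wild type 1 and atino80-6 3 they were 1 up and 3 down (0 and 2 without wild type 1, 0 and 1 without atino80-6 1, 1 and 0 without atino80-6 3). Stomatal lineage markers rose in 2 of 6, TMM 2.12-fold and FAMA 1.39-fold (median 0.40, adjusted p = 0.16; 2 and 0 adjusted over the list alone). Shoot epidermis markers rose in 2 of 7 and fell in 1: LTP1 rose 2.52-fold, CUT1 1.24-fold and PDF1 fell 1.36-fold (median 0.11, adjusted p = 0.59; 2 and 1 adjusted over the list alone). The phloem genes SEOR1 and SUC2 rose 1.78-fold and 1.55-fold among 9 vascular markers, of which 0 fell (median -0.28, mean -0.08, camera up, adjusted p = 0.94; 2 and 0 adjusted over the list alone). Without wild type 1, 4 vascular markers fell (median -0.59). Without wild type 1 and atino80-6 3, 4 fell as well (median -0.70, camera down, adjusted p = 0.22). A single stomatal marker rose without wild type 2, wild type 3, atino80-6 1 or atino80-6 2, and the epidermis counts were 2 up and 2 down without atino80-6 3 and 1 and 1 without any other library. With equal library totals or quantile normalization the epidermis counts turned to 1 up and 2 down, and 1 stomatal marker rose. CUT1 lost its call without any of the 6 libraries (adjusted p at most 0.13, without wild type 3), and with equal library totals (0.054) or quantile normalization (0.055). FAMA lost it without any library except atino80-6 3 (at most 0.15, without wild type 3), with equal library totals (0.072) and after quantile normalization (0.054).

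Of 11 reference genes 2 fell, ACT8 1.34-fold and YLS8 1.17-fold, and 0 rose (median -0.04, adjusted p = 0.35; 0 and 1 adjusted over the list alone). Without wild type 1 and atino80-6 3 they were 1 up and 4 down, without wild type 2 or atino80-6 2 limma called 0, and without wild type 3 or atino80-6 1 it called 1 lower. ACT8 lost its call without wild type 2 or atino80-6 2 (adjusted p at most 0.077), and YLS8 without wild type 2, wild type 3, atino80-6 1 or atino80-6 2 (at most 0.15) and with TMM factors (0.051). Chloroplast-encoded genes rose in 5 of 67 tested members and fell in 2, with ATCG00080 up 3.94-fold, ATCG00070 3.83-fold, ATCG00120 2.45-fold and ATCG00470 2.31-fold (median 0.40, adjusted p = 0.35; 5 and 1 adjusted over the list alone). Without wild type 1 and atino80-6 3 the counts were 5 and 4 (median 0.05), and without atino80-6 3 they were 5 and 6 (median -0.16). They were 5 and 1 without wild type 1, wild type 2 or atino80-6 2. Without atino80-6 1 they were 7 and 1, and the list passed camera with the preset correlation (median 0.70, adjusted p = 0.043). With an estimated correlation and all libraries, camera gave the chloroplast list adjusted p = 0.87. Mitochondrial genes rose in 2 of 26 and fell in 0 (median 0.40, adjusted p = 0.17; 0 and 0 adjusted over the list alone): ATMG00690 2.34-fold and ATMG01390 2.03-fold, with nuclear copies of mitochondrial sequence leaving their source uncertain. That list passed camera with the preset correlation without atino80-6 2 (0.034) and, at a value that rounds to 0.050, without wild type 1. With an estimated correlation and all libraries, camera gave it adjusted p = 0.87. The mitochondrial counts were 0 and 0 without wild type 3 (median 0.16), 1 and 0 without wild type 2, atino80-6 1 or atino80-6 2, and 2 and 1 without atino80-6 3. ATMG00690 lost its call without wild type 2, wild type 3, atino80-6 1 or atino80-6 2 (at most 0.094) and ATMG01390 without wild type 3 (0.053). Organelle reads made up 0.192% of atino80-6 3 and at most 0.0967% of any other library.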

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

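The fit on FPKM values and the fit without wild type 1 and atino80-6 3 were chosen after the data were seen, and the other alternatives before. INO80 stayed higher in the libraries labelled atino80-6 under all 18 alternatives, with log2 changes from 2.35 to 2.51 (limma adjusted p 7.6e-07 to 7.2e-05). The 18 alternatives gave between 2549 and 4435 genes higher and between 2316 and 4384 lower. Leaving out 1 library gave 2549 to 3867 higher and 2316 to 3545 lower genes, 1164 to 1478 higher and 930 to 1184 lower by at least 2-fold, INO80 at 2.39 to 2.51 and 6 to 9 gene lists past the threshold. On FPKM values with a pseudocount of 1, 856 genes were higher and 588 lower by at least 2-fold (1351 and 1073 on normalized counts), where the pseudocount is large beside many FPKM values. Asking for at least 2-fold in limma and in the authors' deposited table left 2336 of 6537 shared calls. Of the gene lists, 7 passed with the settings reported and 0 with an estimated correlation. Among genes with a mean of at least 50, where fewer members are tested, 4 passed. With fry 16 passed, but not the seed storage list, which is among the 7 (fry adjusted p = 0.17). Fry tests whether a list's genes move, on balance, in 1 direction and does not compare the list with other genes. Among genes that passed no test, EIF3E changed sign and was at -0.05 without atino80-6 1, and PORA was at -0.05 without atino80-6 2, and the cause was not tested. Without single libraries EIF3E ranged from -0.05 to 0.19 and PORA from -0.05 to 0.34.

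The share of calls that were higher ranged from 44.3% with equal library totals to 53.7% with TMM factors, and these scalings moved the median of all genes by -0.043 and 0.019 on the log2 scale. With the repeat number as a block, 3158 genes were higher and 2919 lower, 7 lists passed and INO80 stayed at 2.43. Residuals of libraries with the same number correlated at 0.03, -0.19 and -0.10, which gives no sign of pairing. So few libraries cannot rule out a batch shared by repeat number, which the labels do not state. Of 125 named genes past the threshold, 97 kept the call without each library in turn and 28 lost it without at least 1. The other alternatives ended between 0 and 9 of these calls, with 5 ended by equal library totals, 3 by voom, 9 with the repeat number as a block and 9 on FPKM values. The planned edgeR and DESeq2 alternatives were not run, although whole reads were recovered, because count models were reserved for deposited counts; limma voom was fitted to the recovered reads. Depth limits the genes with few reads, since 3 reads in a library are 2.62 to 3.5 normalized counts. Folds against a group with 0 reads are lower bounds, and those against 1 to 3 reads carry wide intervals. Folds against other groups with low means are given without an interval, although few reads limit them too.

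With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3572 higher and 3351 lower genes and 1351 and 1073 at least 2-fold, the highest other split gave 0 of each, and 1 of the 10 splits, the real one, reached each of these counts. For the gene lists the real split gave 7, the highest other split gave 11 (wild type 1 with atino80-6 2 and 3), and 5 of the 10 splits gave 7 or more. Every other split mixes the genotypes and so counts their difference as spread within groups, which by itself keeps gene counts low. The mixed splits therefore do not measure what chance gives for genes. That reason does not account for the lists, where mixed splits reached up to 11. The count of 7 lists under the preset correlation is thus not set apart from that of other groupings. Each mixed split still sets unequal numbers of the genotypes against each other, so it does not measure chance alone for lists either.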

Other observations

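The tests of product families, of library scaling, exchanged labels and run-on transcription for INO80, of cotyledon tissue for the photosynthesis genes with its random sets, and of genes near 0 in 1 genotype were chosen only after the result was seen. Product families named in the reference annotation, tested in the same way as the gene lists, add groups that the lists did not cover. Of 190 families with at least 10 tested genes, 16 passed limma's camera test, 6 higher and 10 lower in the libraries labelled atino80-6. FAD-binding berberine-type oxidases fell in 14 of 18 tested members and rose in 0 (median log2 change -1.02, adjusted p = 0.00013). Fibrillins, which are lipid-associated proteins of plastids, rose in 9 of 10 (median 0.82, adjusted p = 0.00019), and FKBP-type peptidyl-prolyl isomerases in 9 of 13 (0.59, adjusted p = 0.0056). Lipid-transfer and 2S albumin proteins rose in 20 of 47 and fell in 2 (0.45, adjusted p = 0.0020). With an estimated correlation 0 families passed (adjusted p = 0.93 with an estimated correlation for each family named here).

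Among kinase families, some were lower in the libraries labelled atino80-6 and others did not pass. Lectin-domain kinases of the concanavalin type fell in 15 of 28 members and rose in 2 (median -0.64, adjusted p = 0.0031), S-locus lectin kinases fell in 11 of 17 and rose in 2 (-0.92, adjusted p = 0.0068), and leucine-rich repeat kinases fell in 40 of 96 and rose in 12 (-0.24, adjusted p = 0.0068). Leucine-rich receptor-like kinases (2 up and 10 down of 23, adjusted p = 0.12) and leucine-rich repeat transmembrane kinases (2 up and 6 down of 18, adjusted p = 0.68) did not pass. The broad protein kinase superfamily passed camera, with 70 of 258 members lower and 32 higher (-0.17, adjusted p = 0.021). A further family named protein kinase did not pass (1 up and 2 down of 13, adjusted p = 0.72). All kinase families together were not tested as 1 theme. Cysteine/histidine-rich C1 domain proteins fell in 27 of 87 and rose in 3 (-0.46, adjusted p = 0.0020), and VQ motif proteins fell in 10 of 22 (-0.60, adjusted p = 0.0068). GRAS transcription factors fell in 10 of 23 and rose in 1 (-0.30, adjusted p = 0.018). Each family here that passed has adjusted p = 0.93 with an estimated correlation, and members of these families are related in sequence.

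INO80 was 5.40-fold higher in the libraries labelled atino80-6. The tables argue against a uniform rise of the whole region, since the 10 nearest tested genes had a median log2 change of -0.11. Neighbours nevertheless passed the threshold in both directions, and such changes can cancel in a median. Of all tested genes 34.2% passed. Local differences other than a uniform rise were not tested. AGL16 (-0.94), AT3G57280 (-0.47), AT3G57320 (-0.65), ACA11 (-0.59) and AT3G57340 (-0.21) were lower, and AT3G57310 (5.99) and AT3G57350 (0.47) higher. The choice of scaling does not explain the rise, since INO80 stood at 2.38 or higher under the 4 scalings, the reported one included. These scalings moved the median of all genes little, so a larger scaling error was not tested by them. An exchange of all labels between the groups stays open: the gap of 2.19 on the log2 scale between the lowest library labelled atino80-6 and the highest wild type library restates the difference, and no table gives the levels of a line known to be wild type. A candidate explanation with values that go with it is an INO80 locus altered in the libraries labelled atino80-6, whose transcription runs on into AT3G57310, the next gene downstream, which had 0 reads in the 3 wild type libraries and 45.6, 70.7 and 75.1 normalized counts in the others (at least 70.9-fold higher); its log2 change exceeded that of EIF3E, the neighbour on the other side, by 5.93. AT3G57310 lies on the opposite strand and whether the reads kept their strand is not stated, the next gene after it, AT3G57320, stood at -0.65, and this hypothesis was formed on the same data.

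The photosynthesis list had a median log2 change of 2.00. The tables argue against a bias with gene length, since a median of 1.91 was left after the trend was removed. A larger share of cotyledon tissue stays open: the standard deviation of the members' changes (1.22) was 9.13 times their median standard error (0.13), while 10000 random sets of 43 genes had a median ratio of 5.96 and 5.5% of them reached the list's own (99.7% a ratio of 3), and no list held cotyledon markers. Exposure of the seedlings to light before harvest also stays open. ELIP1, ELIP2 and HY5, which light raises, had a median of 1.53, which met the limit written for this explanation. ELIP1 stood at 1.53, ELIP2 at 2.3 and HY5 at -0.29, while PORA, which light lowers, stood at 0.11. A requirement that was no part of the limit written beforehand was added to it and was not met. It asked that ELIP1, ELIP2 and HY5 each rise and PORA fall past the threshold. By the limit as first written, the values go with exposure to light. A change of light-type development by genotype, which the design names, is untested beside these, and the rise may come from any of them.

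Among genes with a mean of at most 5 normalized counts in 1 genotype and at least 50 in the other there were 62, and 61 of them passed the limma threshold. A few chromosome segments that differ between the lines, as the whole cause, would place such genes side by side more often than chance. Many small segments scattered over the genome need not, so the count of neighbours cannot speak to those. Of these genes 2 had another among the 5 tested genes on either side, where random draws gave a median of 2 and 61.3% of draws gave as many. These 2, AT1G65485 (53.2 and 2.1 normalized counts in wild type and atino80-6) and AT1G65490 (3.5 and 128), are both of unknown function, and 0 had a neighbour with another annotated product. Of the 62 genes 45 (72.6%, exact 95% interval 59.8 to 83.1) were abundant in the libraries labelled atino80-6 and 17 in wild type, which may go with genes silent in wild type being switched on, and CYP71A22 and AT3G11110, chosen after their values were seen, had 0 wild type reads against 78.1 and 66.9 normalized counts. Where every library had to lie at most at 3 in 1 genotype and at least at 50 in the other, 12 of 14 genes (85.7%) were abundant in the libraries labelled atino80-6. The 72.6% lay under the limit written as going against silent genes being switched on, although its interval reached over that limit. The 85.7% under the stricter rule lay over it. The shares leave this explanation open, because they would follow from any cause that raises more genes than it lowers.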
